A study of Mus musculus with 4 samples.

How the data were processed

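RNA-seq tables of 4 tumour samples were used, 2 controls and 2 miR-9 knockouts, grouped by the genotype in the labels. Per the labels' protocols, tumours came from female mice of mixed C57BL/6 descent, compared with littermates, RNA was extracted with a TRIzol-type reagent, and libraries were made with an Illumina TruSeq RNA kit and sequenced on an Illumina NovaSeq instrument. The submitters' processing notes name Bowtie 0.12.2 and both human and mouse genome builds, with no role for each. The counting tool, the strand setting, the annotation release and the criteria by which genes were listed are not given in the sources used here.

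Each deposited table held 1142 genes with identifiers, symbols, coordinates and a signal value per gene. The deposited signal values were gene read counts divided by 1 size factor per sample: in each sample 100% of values were whole multiples of the smallest value above 0, to within 1e-06 reads, and division by that value gave whole reads. In control 1 that value, 1.00215, is so near 1 that recovered and rounded reads are harder to tell apart than in the other samples, so its read counts and the floors that use them are less sure. The value of 1 read gave the relative depth of each library, from 0.885 to 1.11, a ratio of 1.25. Reads over listed genes are not the depth of the library, since the table holds a selected part of it. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

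The main test was limma 3.58.1 in R 4.3.3, with a trend, on log2(value + 1), for genes with a mean of at least 0.5 over the 4 samples, with genotype as the single term, 2 residual degrees of freedom and Benjamini-Hochberg adjustment over the 1142 genes at 0.05. No gene lay below the minimum: 0 were removed. Log2 changes are on that scale and understate the change of genes with low values, and SE is the standard error of the log2 change. Before the data were examined, a count test was planned for counts and limma for normalised values, and the latter applied. Folds are ratios of group means. Where a group had no read, the fold is a lower bound against a floor of 3 reads over the group's 2 samples together, and where it had 1 to 3 reads the ratio is given with an exact Clopper-Pearson 95% interval.

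The genes named were set by a rule written before the data were examined: among genes past the threshold with both knockout samples on the same side of both controls and a mean of at least 1 in the higher group, leaving out predicted genes, the 10 largest changes in each direction, up to 4 members of each gene list and any miR-9 locus transcript. The rule took 95 genes. Other list members, Fgfr2, Gm23935, Lars2 and the genes of the closing observations were named outside it. The values of some list members are not reported here.

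The 32 gene lists (pathways and cell-type markers) were fixed before the data were examined, and 21 had at least 3 members in the table. Since the table holds selected genes and has no background, camera and fry were not run. The direction of members that passed was compared with that of the remaining genes that passed by a two-sided Fisher's exact test, adjusted over the 21 lists. In each alternative setting the adjustment covered only lists with at least 3 members called, which were fewer than 21 under TMM and RLE. Its units are genes, which can move together and were measured in the same 4 samples, so its p does not measure replication over tumours. Seed sites were searched in the longest 3' UTR of protein-coding transcripts of GENCODE M21 (GRCm38), in which 1141 of the 1142 gene identifiers were found, 1097 with identical chromosome, start and end. A 3' UTR was annotated for 1043 genes (91.3%). The odds ratio of a site was ranked among 527 other 7mers with a frequency within 10% of that of the miR-9 sites.

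The limma script was tested on simulated counts drawn from the means and depths of these samples, with 200 of 1142 genes changed: it called 32%, 78%, 100% and 100% of genes changed by 1, 2, 3 and 4 on the log2 scale (50 genes each), and 14 of 942 unchanged genes (1.5%). The simulated genes were not selected for difference, as the listed genes were. Those rates therefore check the script and say nothing of the error among the listed genes. The replicates were compared before they were averaged. Chi-square per degree of freedom was 55.8 between the controls and 13.8 between the knockouts, so no pair differed by as little as sampling noise. The correlation across genes, which are not independent replicates, was r = 0.922 between the controls and 0.976 between the knockouts.

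Alternatives were pseudocounts of 0.1 and 5, no filter and a minimum mean of 5, a threshold of 0.01 or an added log2 change of 1, a term for the replicate number, leaving out each sample, and tests on recovered reads with DESeq2 1.42.0, limma-voom and edgeR 4.0.16 with other scalings. Figures and list tests used Python 3.11.15 and scipy 1.17.1.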

Results

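RNA was sequenced from 4 tumour samples of female MMTV-PyMT mice, 2 without a miR-9 knockout (controls 1 and 2) and 2 with it (knockouts 1 and 2). MMTV-PyMT mice carry the middle T antigen of mouse polyoma virus under a mammary tumour virus promoter and develop mammary tumours. miR-9 is a microRNA, a short RNA that pairs through its seed with sites in messenger RNAs and represses them, and the labels describe the knockout as one of miR-9 exon 1. The comparison asked which tumour transcripts differed with the knockout. The tables held normalised read counts of the same 1142 genes in every sample, of which 1043 were protein-coding, and every gene differed at least 2.0-fold between the group means, so the table is a list selected by the study on these samples and not the whole transcriptome. Relative depth, from the value of a single read, was 0.998 and 0.885 in the controls and 1.11 and 1.04 in the knockouts. The listed genes held 512574, 458335, 694925 and 697334 reads in controls 1 and 2 and knockouts 1 and 2. None of the 6 miR-9 locus transcripts looked up was in the table, so the knockout itself was not analysed here. Nothing in the labels says how many animals or tumours the 2 samples of a group came from, so p-values measure only the spread between these samples.

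In knockout tumours the listed hypoxia-response genes and all but 1 of the listed skeletal muscle genes were lower. These were the 2 gene lists whose direction differed from the rest of a table in which 61.3% of genes were higher. That test counted genes and not tumours, and used the deposited scaling. Single genes of luminal, myoepithelial and milk function also changed, although their lists did not differ in direction from the rest with the deposited scaling. Foxa1, which opens chromatin for the oestrogen receptor, rose 13.9-fold, from 129 ± 73.3 to 1789 ± 452 normalised reads (mean ± SD, n = 2 per group, as for all values of this form here). Myh11, the smooth muscle myosin heavy chain, rose 8.48-fold, from 570.0 ± 434 to 4830.1 ± 121, and Csn2, beta-casein, fell 25.3-fold, from 2182 ± 2466 to 86.3 ± 79.9. Vegfa, the vascular growth factor induced by low oxygen, fell 3.25-fold, from 2688 ± 1200.2 to 827 ± 40.4. The adjusted p from limma was 0.0013 for Foxa1, 0.00248 for Myh11, 0.00699 for Csn2 and 0.00709 for Vegfa. The size of the fall of Csn2 rested on control 2: without it the log2 change was -2.72, against -4.3 with all samples.

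**Figure D1:**
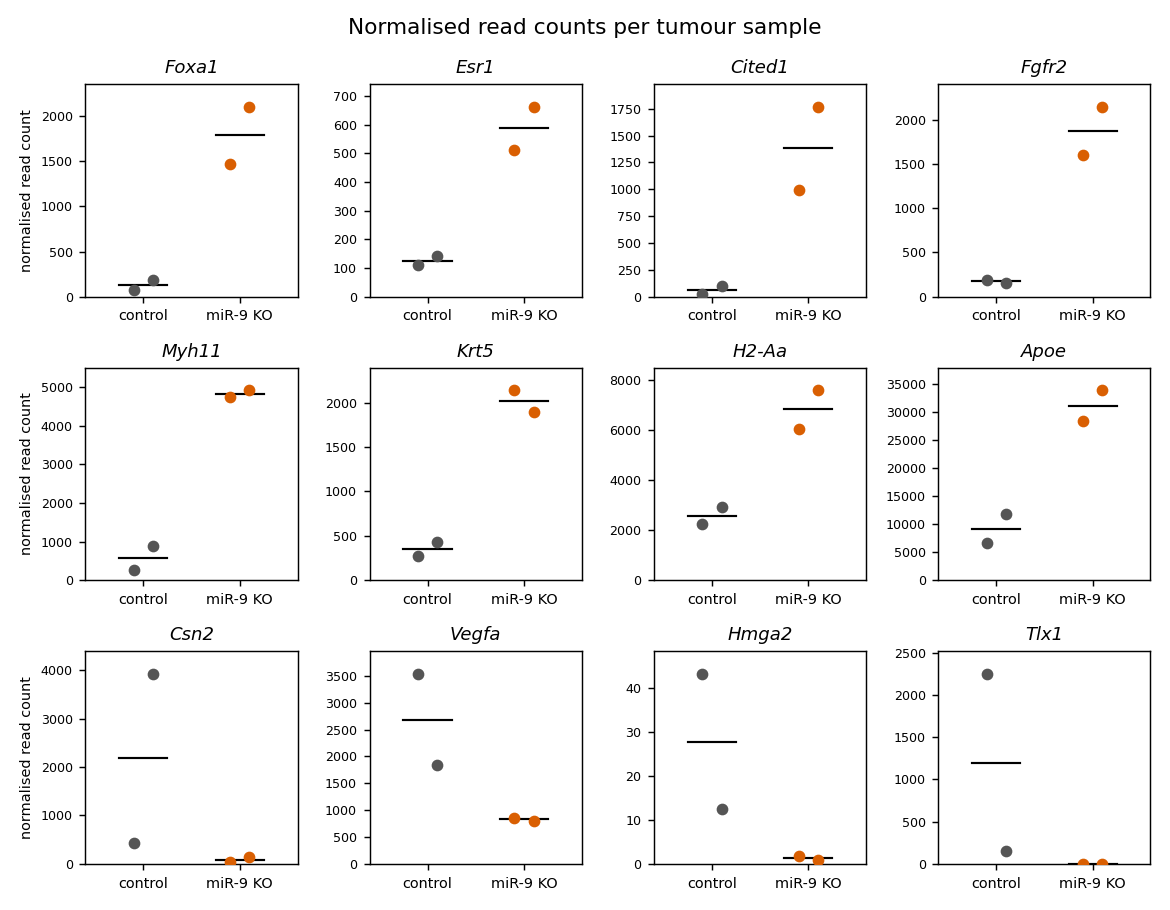
Normalised read count (vertical axes, linear, from 0) of 12 genes in each tumour sample, with controls in grey, miR-9 knockouts in orange and horizontal bars at the group means of 2 samples. Foxa1 lay at 77.2 and 181 in the controls and at 1469 and 2109 in the knockouts, while Tlx1 lay at 2251 and 149 in the controls and at 3.61 and 0.959 in the knockouts.

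Of the 1142 listed genes, 700 were higher and 440 lower in knockout tumours at a limma adjusted p under 0.05, and 2 did not pass. The 2 were Mylk2, at 162 and 18.1 in the controls against 12.7 and 13.4 (limma adjusted p = 0.0595), and Capn11, at 119 and 5.65 against 3.61 and 6.71 (limma adjusted p = 0.101). In 1141 genes both knockout samples lay on the same side of both controls, an arrangement that chance gives to 33.3% of genes. The median log2 change was 1.70 over the higher genes and -1.63 over the lower ones. A change of at least 2 on the log2 scale was seen in 260 higher and 172 lower genes. Because the study picked the table for difference between these samples, the counts and directions are not independent evidence. The adjusted p-values do not allow for that selection either. A call over all genes means over these 1142 selected genes, of which 1140 were called. That a list member was called therefore adds little. Without knockout 1, 13 genes passed the limma test, and without knockout 2 also 13, all of them higher. Scaling on the listed genes themselves moved the share of higher genes among those called from 61.4% to 35.9% (TMM), 24.3% (RLE), 51.3% (upper quartile) and 55.2% (totals), and the median log2 change of all listed genes from 1.23 to 0.48, 0.13, 0.79 and 0.88, so every direction here is relative to the deposited size factors.

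The largest increases were in genes near the floor of detection in the controls and in a few abundant ones. Fgb, the beta chain of fibrinogen, rose 39.6-fold, from 82.7 ± 71.6 to 3273 ± 1080.4 (log2 change 5.58 ± 0.60 SE; limma adjusted p = 0.0011). Ido1, which degrades tryptophan, rose 28.8-fold, from 10.2 ± 3.12 to 294 ± 4.41. Cxcl15, a chemokine, rose 27.6-fold, and Reln, the extracellular glycoprotein reelin, rose 27.3-fold, from 26.0 ± 24.0 to 710.0 ± 44.2. Cyp3a57, a cytochrome P450, had 3 reads in the controls and 399 in the knockouts, a ratio of 116 (95% counting interval 39.6 to 567). Tenm2, a teneurin, had 1 read against 92, a ratio of 80.6 (14.1 to 3217). No control read fell on Slc44a5, Lmntd1, Sbp or Tescl, which were at least 60.7-fold, 26.9-fold, 16.8-fold and 16.5-fold higher, against a floor of 3 reads over the 2 controls together.

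The largest decreases included 3 homeobox transcription factor genes of chromosome 19. Lbx1 (ENSMUSG00000025216, chromosome 19, 45232684 to 45235812, minus strand, GRCm38) had 239 and 156 normalised reads in the controls and no read in either knockout, at least 141-fold lower. Nkx2-3 (ENSMUSG00000044220, 43612325 to 43615892, plus strand) had 51.1 and 279 and no read, at least 118-fold lower. Tlx1 (ENSMUSG00000025215, 45150680 to 45156943, plus strand) fell 525-fold, from 2251 and 149 to 3.61 and 0.959 (limma adjusted p = 0.00199). Tlx1 overlaps the antisense gene Tlx1os (45154057 to 45159304, minus strand) in part, from 45154057 to 45156943. The kit is not stated to keep strand, so reads from that stretch cannot be told apart. Reads outside the stretch were not counted separately. Sez6 fell 37.3-fold, from 698 ± 417 to 18.7 ± 6.05, Fndc3c1 45.4-fold and Xkr6 26.2-fold.

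Luminal genes rose together with genes of the hormone response. The lists share members, Foxa1 and Esr1 among them, so they are not separate evidence. All 5 listed members of the luminal epithelium list rose (22 genes fixed; 5 called over all genes and 5 adjusted over the list alone): Foxa1, Esr1, Spdef, Prlr and Krt19. Esr1, oestrogen receptor alpha, rose 4.7-fold, from 125 ± 22.6 to 588 ± 106, and Prlr, the prolactin receptor, rose 3.92-fold, from 1142 ± 288 to 4470.2 ± 884. Of 18 genes fixed for oestrogen receptor and luminal hormone signalling, 7 were listed and all 7 called, 6 higher and 1 lower, over all genes and adjusted over the list alone. Cited1, a transcriptional co-activator, rose 22.2-fold, from 62.2 ± 52.6 to 1384 ± 547, and Wnt4, a ligand induced by progesterone, rose 8.98-fold, from 31.0 ± 4.12 to 278 ± 84.0. Stat5a also rose, but its sign turned under RLE scaling on the listed genes, and Greb1, an oestrogen-induced gene, fell 2.57-fold, from 125 ± 3.82 to 48.7 ± 7.83. Fgfr2, singled out after its values were seen, rose 10.9-fold, from 171 ± 29.8 to 1874 ± 388. The share of members higher did not pass the test against the rest of the table (two-sided Fisher's exact test, adjusted over 21 lists: p = 0.571 for luminal epithelium and 0.582 for hormone signalling). With RLE factors from the listed genes both passed, at adjusted p of 0.0424 and 0.0175, with 3 of 5 and 5 of 7 members called higher, because these factors removed more of the higher calls from the rest of the table. Under RLE fewer than 21 lists had at least 3 members called and entered the adjustment. Adjusted over 21 lists, both values would be larger.

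Milk genes moved the other way. Of 20 milk and lactation genes fixed, 5 were listed and all 5 called, also when adjusted over the list alone, 4 lower and 1 higher. Glycam1, a mucin-like milk protein, fell 339-fold, from 1119 ± 1010.3 to 3.30 ± 2.11, Csn1s2a 48.5-fold, from 1293 ± 1466 to 26.6 ± 5.72, and Csn1s1 9.7-fold. The controls were far apart: Csn2 was at 439 and 3926 and Glycam1 at 405 and 1834 in controls 1 and 2. Without control 2 the log2 change of Csn2 was -2.72, against -4.3 with all samples. Cd36, a fatty acid transporter, rose 3.1-fold, from 55.1 and 88.1 to 102 and 342 (limma adjusted p = 0.0407), a call lost with a pseudocount of 0.1, without either control, and under TMM, RLE and upper-quartile scaling on the listed genes. Of the 4 fallers 3 were called without control 2, and none of the 5 without either knockout. Fisher's exact test of direction gave an adjusted p of 0.4 for this list.

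Contractile genes of the basal and myoepithelial list rose. Myh11, Cnn1 and Acta2 are also genes of smooth muscle, so the cells that their transcripts came from cannot be told here. Of 18 basal and myoepithelial genes fixed, 10 were listed, 9 rose and 1 fell, with 10 called over all genes and 10 adjusted over the list alone. Besides Myh11, the risers included Cnn1, calponin 1, at 547 ± 449 against 3334 ± 131 (6.1-fold), Acta2, smooth muscle actin, at 2206 ± 1183 against 11826 ± 103 (5.36-fold), Krt5, a basal keratin, at 353 ± 108 against 2016 ± 175 (5.71-fold), and Oxtr, the oxytocin receptor (3.86-fold). Krt14, the keratin that pairs with Krt5, fell 2.38-fold, from 3259 ± 1037 to 1370 ± 36.9. The direction of the list did not pass Fisher's exact test against the rest (adjusted p = 0.416). It passed with TMM (0.0192) and RLE (0.00958) factors from the listed genes, although 8 and 6 members were then called higher, fewer than the 9, for the same reason as with the luminal lists.

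Markers of other cell types moved in the same samples. The table held 4 of 20 adipocyte genes fixed, 7 of 22 macrophage, 3 of 22 T and NK cell and 3 of 18 B and plasma cell genes. It also held 5 of 14 dendritic cell and MHC class II, 4 of 12 Schwann cell, 4 of 20 fibroblast, 4 of 15 salivary gland and 2 of 19 skin and hair genes. The levels of the members left out are not known. All 4 listed adipocyte genes rose, among them Lep, leptin (14.1-fold, from 7.15 ± 5.86 to 101 ± 56.2), and Plin1, a lipid-droplet coat protein (12.5-fold, from 15.8 ± 9.60 to 197 ± 183), but 1 of the 4 passed without control 1 and 2 without control 2, and the median log2 change was 3.80 without knockout 1 and 2.12 without knockout 2. All 7 listed macrophage genes rose, such as Apoe, 9181 ± 3703 against 31089 ± 3841 (3.39-fold), and Csf1r, the receptor for macrophage colony-stimulating factor, 600.0 ± 209 against 1424 ± 88.6 (2.37-fold), but C1qa and C1qc changed sign under RLE scaling on the listed genes, and 1 of the 7 was called under TMM, 1 under the upper quartile and 0 under RLE, and 5 without control 1. The 3 listed T and NK cell genes rose (Gzmb 3.81-fold, Nkg7 3.8-fold, Gzma 3.3-fold), as did the 3 listed immunoglobulin heavy chain genes (Ighg1 6.63-fold, Ighm 4.7-fold, Ighg2b 3.27-fold), 2 of them called under TMM and under RLE. Of 5 dendritic cell and MHC class II genes, H2-Aa, H2-Eb1, H2-Ab1 and Cd74 rose 2.29-fold to 2.64-fold, and Fscn1, an actin-bundling protein, fell 2.34-fold. None of those 4 was called higher under TMM or RLE scaling on the listed genes, and of the 3 T and NK cell genes 1 was called under TMM, 0 under RLE and 2 without control 1. Schwann cell genes Cdh19 (6.32-fold) and Ngfr (6.18-fold) rose and Mal fell, with a log2 change of -0.75 without control 2 against -1.24 with all samples. Of the 3 Schwann cell genes that rose 2 were called under TMM and 1 under RLE, where Ngfr was not called. Fibroblast genes Dcn (3.7-fold), Sparc and Mmp2 rose while Fn1, fibronectin, fell 2.01-fold, with 1 of those 3 risers called under TMM and 0 under RLE. In the salivary gland list Prol1, Egf and Prlr rose and Dcpp3 fell, but Dcpp3 was not called without control 1 (limma adjusted p = 0.0676) or without control 2 (0.0761), nor Prol1 without control 1 (0.0977) or under TMM or RLE. In the skin and hair list Krt71 rose, a call lost under TMM and RLE, and Krt79 fell. Every listed member named in these lists was called both over all genes and adjusted over the list alone. That follows from the selection, since 1140 of the 1142 listed genes were called. The macrophage list gave p = 0.0478 and an adjusted p of 0.334 by Fisher's exact test of direction, and the adjusted p was 0.582 for adipocyte, T and NK cell and B and plasma cell genes, 0.916 for MHC class II genes and 1 for Schwann, fibroblast and salivary genes. No member of the endothelium, neutrophil or red blood cell lists was in the table, which says nothing of their levels.

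Skeletal muscle genes fell. Of 22 genes fixed, 11 were listed and all 11 called, also when adjusted over the list alone, 10 lower and 1 higher. Acta1, skeletal muscle actin, fell 26.3-fold, from 431 and 384 to 26.2 and 4.79, and Tnnt3, fast troponin T, also 26.3-fold, from 24.1 and 143 to 5.42 and 0.959. Ckm, muscle creatine kinase, fell 18.9-fold, and Atp2a1, the calcium pump of fast muscle, 9.8-fold. Myh1 had 59 reads in the controls and 1 in the knockouts, a ratio of 67.4 (11.6 to 2705). Tpm2, a tropomyosin that smooth muscle also makes, rose 2.38-fold. By Fisher's exact test, with genes as its units, the list was lower more often than the rest of the table (adjusted p = 0.0052). That p was 0.0502 with TMM and 0.222 with RLE factors from the listed genes, settings under which all 10 members were still called lower. The median log2 change of the 11 members was -3.41 with all samples, -4.47 without control 1 and -2.35 without control 2.

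Hypoxia and glycolysis genes fell without exception among those listed. Of 22 fixed, 10 were in the table and all 10 fell, 10 of them also adjusted over the list alone. Without control 1, 7 of the 10 passed (median log2 change -0.90), without control 2 all 10 (-1.68), and without either knockout 0. P4ha2, a collagen prolyl hydroxylase, fell 4.75-fold, from 788 ± 175 to 166 ± 18.8, and Car9, carbonic anhydrase 9, fell 3.79-fold, from 1736 ± 275 to 458 ± 63.1. Adm, adrenomedullin, fell 3.4-fold, Egln3, an oxygen-sensing hydroxylase, 2.6-fold, Pfkfb3, a regulator of glycolysis, 2.42-fold, and Pgk1, phosphoglycerate kinase, 2.04-fold, from 8525 ± 3147 to 4170 ± 89.0. Fisher's exact test of direction, with genes as its units, gave p = 6.9e-05 and an adjusted p of 0.00145. The adjusted p was 0.0502 with TMM and 0.222 with RLE factors from the listed genes, under which all 10 members were still called lower.

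**Figure D2:**
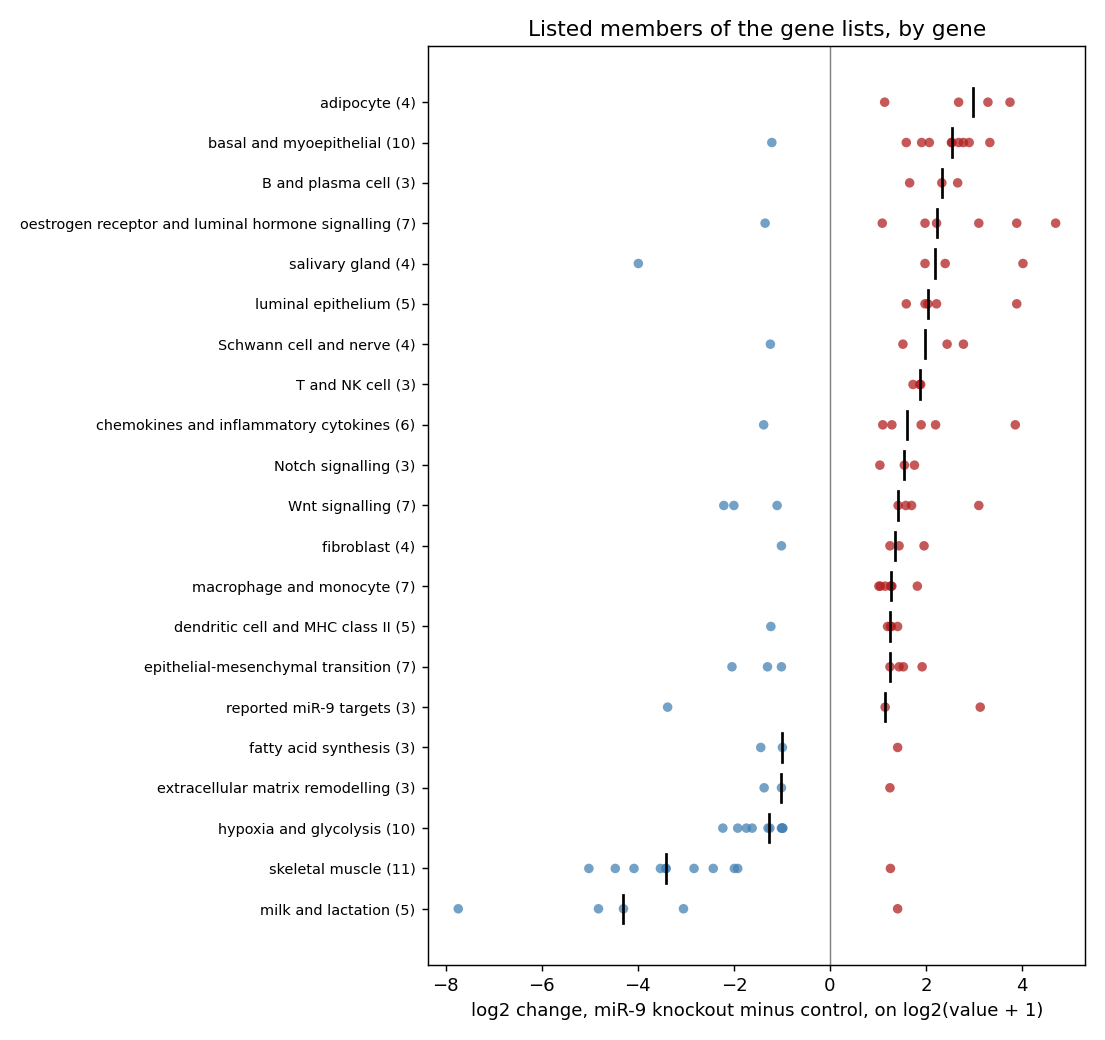
Log2 change, miR-9 knockout minus control on log2(value + 1), of each listed member of the 21 gene lists with at least 3 members in the table. Each point is a gene (red higher, blue lower), black bars mark list medians and the number of members is in brackets; all 10 hypoxia and glycolysis genes lie below 0, and C1qa, C1qc, Stat5a and Jag2 lie above 0 but changed sign under RLE scaling on the listed genes.

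Signalling lists went both ways. The table held 3 of 18 Notch genes fixed, 7 of 22 of the epithelial-mesenchymal transition, 6 of 28 chemokines and cytokines and 3 of 24 matrix remodelling genes. It also held 3 of 18 fatty acid synthesis, 2 of 20 stem-cell, 1 of 28 cell-cycle and 1 of 19 p53-response genes. In the Wnt list, of 23 fixed and 7 listed, 4 rose and 3 fell: Wnt5a rose 2.63-fold, Dkk3 2.69-fold and Nkd1 3.19-fold, while Wif1, a secreted Wnt inhibitor, fell 3.98-fold, Ctnnb1, beta-catenin, 2.15-fold, from 22851 ± 1765 to 10633 ± 1011, and Rspo1 6.89-fold, from 181 and 30.5 to 14.5 and 16.3. The fall of Rspo1 rested on control 1: without it the log2 change was -0.95 (limma adjusted p = 0.0656) against -2.21 (0.0229), and limma-voom gave an adjusted p of 0.0508. All 3 listed Notch genes were called higher, Jag1 (2.91-fold), Hey2 (2.98-fold) and Jag2 (2.05-fold), the last with its sign turned under RLE scaling on the listed genes, where 0 of the 3 were called, against 1 under TMM and 1 under the upper quartile. In the Wnt list 1 member was called higher and 3 lower under TMM and under RLE. Among genes of the epithelial-mesenchymal transition 4 rose, with Cdh2, N-cadherin, 3.31-fold and Snai2, a repressor of E-cadherin, 2.88-fold, and 3 fell, with Itga5 2.79-fold. In that list 0 were called higher and 3 lower under TMM and under RLE, and 2 higher and 2 lower without control 1. Among chemokines and cytokines Cxcl13 rose 11.6-fold, Cxcl14 4.44-fold, Ccl8 3.77-fold, Cxcl12 2.4-fold and Il33 2.16-fold, and Lif fell 2.67-fold, with 3 of the 5 risers called without control 1, 2 under TMM and 1 under RLE. Of 3 matrix remodelling genes Mmp2 rose and Fn1 and Adamts4 fell, and of 3 fatty acid synthesis genes Dgat2 rose and Elovl5 and Mlxipl fell, with 0 higher and 1 lower called without control 1 and 0 and 2 without control 2. Neither Mmp2 nor Dgat2 was called under TMM or RLE. Without control 1 the log2 change of Adamts4 was -0.73, against -1.37 with all samples. The stem-cell list had Aldh1a3 (3.79-fold) and Aldh1a1 (2.63-fold), both higher, with 1 called under TMM and 0 under RLE. Ccne1, cyclin E1, was the 1 listed cell-cycle gene and fell 3.02-fold, Eda2r was the 1 listed p53-response gene and fell 2.62-fold, and the heat shock genes Hsph1 and Hspa1a fell 2.56-fold and 2.01-fold. All listed members of these lists were called over all genes and adjusted over the list alone. Fisher's exact tests of direction gave adjusted p of 0.582 (Notch), 0.726 (chemokines), 0.844 (matrix and fatty acid) and 1 (Wnt and epithelial-mesenchymal transition). The interferon and cholesterol synthesis lists had no member in the table.

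Of 39 genes fixed as reported miR-9 targets, 3 were in the table, 2 higher and 1 lower, all 3 called over all genes and adjusted over the list alone. Id4, an inhibitor of basic helix-loop-helix factors, rose 8.06-fold, from 120.0 ± 69.5 to 970.0 ± 79.1 (log2 change 3.13 ± 0.44 SE; limma adjusted p = 0.00182), and Tgfbr2, a TGF-beta receptor, rose 2.13-fold, from 2296 ± 897 to 4891 ± 62.6. Hmga2, a chromatin protein, fell, with 54 reads in the controls and 3 in the knockouts, a ratio of 20.5 (6.67 to 103; limma adjusted p = 0.00962). Under TMM and RLE scaling on the listed genes 1 of the 3 was called higher and 1 lower. Tgfbr2 was not called under TMM, RLE, upper-quartile or totals scaling, with log2 changes of 0.38, 0.04, 0.68 and 0.76. Sites for the miR-9-5p seed, ACCAAAG or CCAAAGA, stood in the longest annotated 3' UTR of 177 of 648 higher genes (27.3%) and 92 of 393 lower genes (23.4%). The odds ratio was 1.23 (95% interval 0.911 to 1.66; two-sided Fisher's exact p = 0.166). Median 3' UTR length was 1260.5 bases in higher and 934 in lower genes, and with genes matched on that length the odds ratio was 1.02 (0.691 to 1.5).

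A very short gene and a gene that moved with it also differed between the groups. Gm23935, a gene of 57 bases annotated as a microRNA on chromosome 16 (11144125 to 11144181), was the most abundant listed gene in both controls, at 48934 and 34385 against 15326 and 18400 in the knockouts, and took 9.53% and 6.64% of the controls' listed reads against 2.44% and 2.75%. Reads on Lars2, the gene of mitochondrial leucyl-tRNA synthetase, followed it, at 14600 and 9230 against 4521 and 5525. Whether those reads came from Lars2 messenger RNA was not tested. Both were singled out after their values were seen, with limma adjusted p of 0.0135 and 0.0137. The controls were also less alike than the knockouts, with an SD over genes of the log2 difference between the samples of a group of 0.998 against 0.553.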

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

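The edgeR tests on recovered reads with the deposited factors and with TMM factors from the listed genes were chosen after the data were seen. Against 1140 genes past the threshold, other pseudocounts gave 1137 and 1139, limma-voom 1136, DESeq2 1141, edgeR with the deposited factors 1142 and an added log2 change of 1 gave 1129. Both low-value filters removed 0 genes and so tested nothing. Scaling factors taken from the listed genes gave fewer: 690 with TMM (248 higher, 442 lower), 584 with RLE (142 higher, 442 lower), 908 with the upper quartile (466 higher) and 986 with totals (544 higher). Such factors assume that most listed genes did not differ, which a table selected for difference does not meet, and they lower the log2 change of all genes alike. At an adjusted p under 0.01, 584 genes passed, 387 higher and 197 lower. Leaving out 1 sample gave 13 to 1070 genes, 13 to 665 higher and 0 to 405 lower: 990 without control 1, 1070 without control 2 and 13, all higher, without knockout 1 or without knockout 2. In those last 2 fits the lone knockout is assumed to vary like the controls, which varied more. In the fits without control 1 or without control 2 the lone control is assumed to vary like the knockouts, which varied less. The SD over genes of the log2 difference within a group was 0.998 in the controls and 0.553 in the knockouts. The number of genes passing in any of these fits therefore does not measure how stable a result is. Of the named genes 14 and 7 no longer passed without control 1 and control 2, 25 under TMM, 33 under RLE, 11 under the upper quartile, 4 under totals, and 1 under limma-voom. Under RLE Jag2 turned to -0.07, which the shift common to all genes accounts for. The number of lists past the threshold, 2, was 1 with TMM (basal, adjusted p = 0.0192), 3 with RLE, and 0 to 2 when a sample was left out, 0 without either knockout. The 3 under RLE were other lists, basal (0.00958), hormone signalling (0.0175) and luminal epithelium (0.0424), which had no more members called higher than before and passed because higher calls elsewhere fell, while hypoxia and muscle no longer passed under TMM (0.0502 each) or RLE (0.222 each). The odds ratio of seed sites was 1.01 with 8mer sites alone and 1.02 when matched on length. The camera test with an estimated correlation was not run, for lack of a background. Depth limits the folds of genes with 3 reads or fewer in a group.

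The fit with the number of the sample as a replicate block called 1142 genes, 700 higher and 442 lower, 2 lists past the threshold, and a seed-site odds ratio of 1.24. With 2 pairs, the deviations of same-numbered samples correlated at r = 0.043 across genes, which gives no sign of pairing but cannot exclude it, and the labels do not say that a number pairs samples.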

Other observations

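The sets of smooth muscle, replication, carrier and plasma protein genes, the transcription factor families and the tests on chromosome 19, skeletal muscle, cell-type markers and genotype were chosen only after the result was seen, and the tests on gene families and copy number after the first result on directions along chromosomes.

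Genes of smooth muscle contraction were higher: of 12 members of a set chosen after the values were seen, all called higher, 5 belong to the fixed lists and 7 do not, among the latter Jph2 (6.71-fold, 56.6 ± 31.8 against 380.0 ± 12.4, mean ± SD, n = 2), Tgfb1i1 (4.2-fold), Kcnmb1 (4.33-fold) and Myl9 (3.49-fold, 1176 ± 3.33 against 4100.0 ± 131). All 12 genes of a DNA replication and repair set, 11 of them outside the fixed lists, fell (median log2 change -1.08), such as Mcm10 (2.35-fold, 578 ± 141 against 246 ± 30.5), Orc1 (2.42-fold) and Polq (2.1-fold), and so did 7 carriers of monocarboxylates and amino acids, among them Slc16a1 (3.41-fold, 1693 ± 42.2 against 496 ± 66.1), Slc16a3 (4.31-fold) and Slc6a15 (6.09-fold). Plasma proteins best known from the liver went both ways, 10 higher and 4 lower: Fgg, the gamma chain of fibrinogen, rose 18.0-fold with Fgb, Proc rose 24.5-fold and Itih2 13.4-fold, while on chromosome 16 Ahsg (9.14-fold), Fetub (7.53-fold) and Kng2 (8.75-fold) fell and Masp1, which lies near them (23449417 to 23520815; Kng2 at 22985854 to 23029482), rose 5.54-fold, from 27.8 ± 16.6 to 154 ± 26.5. These sets were picked from the table, so their counts have no test.

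Among transcription factors, 10 of 13 C2H2 zinc finger genes in the table fell and 3 rose (Fisher's exact p = 0.00723, adjusted over 3 families 0.0217). The families were chosen after the values were seen, so the adjustment does not cover that choice. Directions are again relative to the deposited size factors. Homeobox genes went both ways, 11 higher and 6 lower (adjusted p = 1 by Fisher's exact test). Irx4 rose 9.07-fold, Pdx1 10.7-fold and Dlx5 5.19-fold, and Hoxc10, with no control read, was at least 11.1-fold higher, whereas Prrx2 fell 5.99-fold and Dlx3 7.06-fold. Of 9 bHLH genes 7 rose and 2 fell (adjusted p = 0.743 by Fisher's exact test), 1 of them, Arntl, with a sign that turned under RLE scaling on the listed genes.

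Listed markers of several other cell types were higher in the knockouts, and a lower share of tumour cells is a candidate explanation. In the basal, adipocyte, fibroblast, macrophage, T and NK cell, B and plasma cell, MHC class II and Schwann cell lists, 36 of 40 listed members were higher and 4 lower, with list medians 1.72 apart on the log2 scale (1.26 for MHC class II, 2.98 for adipocyte), while 10 of 11 skeletal muscle members fell. The luminal epithelium list, which is not among these lists, also rose in all 5 listed members (median log2 change 2.04). Whether those luminal transcripts came from tumour cells was not measured. The study selected these members for the size of their difference, and the adipocyte median was 2.12 or 3.80 depending on the knockout left out, so a lower share of tumour cells cannot be told apart from changes within each cell type. Nor can the genotype be told apart from any other difference between the groups, with 2 samples in each.

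Skeletal muscle genes were lower in the knockouts, and a candidate explanation is muscle tissue in the control samples. Of the 11 listed members of the list, 0 belong to another list, and all were selected by the study. Over the 10 members that fell the log2 ratio of control 2 to control 1 ran from -1.63 (Ryr1) to 2.58 (Tnnt3) with an SD of 1.37, was -0.17 for Acta1, the most abundant of them at 431 and 384, and lay between 1.03 and 2.58 for the other 8. Muscle of 1 composition in both controls would keep 1 ratio, but the composition of any muscle in either sample was not measured, so muscle tissue cannot be told apart from other sources. No biological explanation of the lower muscle genes was tested.

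Lbx1, Tlx1 and Nkx2-3 lie within 2 Mb of chromosome 19 and were all but absent from the knockouts. With fold changes permuted over the listed protein-coding genes, 3 genes at a log2 change of -6 or lower fell within 2 Mb in a share of 0.0001, the smallest that 10000 permutations can give. Both bounds were set after the genes were seen, and only 4 genes reached -6. That share therefore restates the observation and does not measure how rare it is. Reads shared with the antisense gene concern Tlx1 alone, since neither Lbx1 nor Nkx2-3 overlaps Tlx1os. Between the controls these 3 genes did not vary together. The log2 ratio of control 1 to control 2 was 3.92 for Tlx1, 0.61 for Lbx1 and -2.45 for Nkx2-3. More widely, 340 of 558 neighbouring listed genes within 1 Mb shared a direction against 293.1 in permuted directions (p = 0.0001, again the smallest possible), and 287 of 499 against 262.1 with overlapping genes and shared symbol stems left out (permutation p = 0.014). Pairs 2 to 10 Mb apart shared a direction no more often than permuted (an excess of -0.45 percentage points, SD 0.83, against 8.4 within 1 Mb). That gives no sign of many segments of several Mb that changed expression at least 2.0-fold. Segments with smaller changes would leave few genes in the table, and a few segments would be lost among 4253 pairs. The test therefore cannot exclude copy-number differences, and local co-regulation is an untested hypothesis.

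Loss of repression through miR-9 sites was tested as a hypothesis for the genes that rose. The odds ratio of carrying a site, 1.23, stood at the 47.8th percentile of the other 7mers of like frequency, and the median log2 change of genes with a site exceeded that of genes without by 0.01 (26.9th percentile). The interval of the odds ratio, 0.911 to 1.66, leaves a modest excess open, and a table selected at 2.0-fold holds few of the small changes that a microRNA usually makes, so the hypothesis is neither borne out nor excluded.

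Some values stand without an explanation. The ratio of Lars2 to Gm23935 was 0.298, 0.268, 0.295 and 0.300 in controls 1 and 2 and knockouts 1 and 2. The fall of Lars2 can therefore not be told apart from that of Gm23935. Gm24270, like Gm23935 annotated as a microRNA, also fell, from 560.0 and 566 to 179 and 265, and mt-Co3 fell 2.18-fold.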
